A study of Strongylocentrotus purpuratus with 12 samples.

How the data were processed

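Gene expression was measured in pluteus larvae of the purple sea urchin Strongylocentrotus purpuratus, the feeding larval stage of this animal. Larvae were raised at 13 or 18 °C, each at a pCO2 (partial pressure of carbon dioxide) of 400 or 1100 µatm, with 3 replicate cultures per combination. Per the labels, about 8000 larvae were pooled for each of the 12 samples, RNA was extracted with Trizol, and 200 ng of it was labelled. Each array of an Agilent custom design carried the culture's RNA in Cy5 and a pool made from aliquots of all samples in Cy3. The dyes were not swapped on any array.

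Per the file headers, the authors quantified the scans with Agilent Feature Extraction, and the deposited scanner files hold the mean intensity of each spot and the median intensity of its local background in both dyes. The same files hold processed intensity values, which were background-subtracted, spatially detrended and dye-normalized by that software and are the basis of a log10 ratio column. Per the file headers and the values, the deposited log10 ratio is that of processed Cy5 over processed Cy3 intensity, computed by Feature Extraction. Feature Extraction set the log10 ratio of 60.1% of spots to 0, so that column was not used. The series table deposited by the authors holds log2 ratios for 3627 targets. Its normalization is not stated. Its scale was read from the values, and the medians of its columns lie between -0.065 and 0.041.

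Each array had 105072 spots, of which 1325 were controls. The 103747 other spots held 103612 probes of 60 bases with 85271 distinct sequences, for 28819 targets named by SPU identifiers, the gene models of the purple sea urchin genome. Spot and background intensities were combined by normexp background correction with an offset of 50 and normalized within each array by loess in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Control spots and spots marked as outliers by the scanner software were left out. Log2 ratios of Cy5 over Cy3 were averaged over the spots of a probe and then over the probes of a target. A probe was kept if its Cy5 signal was well above background, by the software's own mark, on at least 3 of the 12 arrays. This left 26583 probes for 10430 targets, with at most 4 probes per target. The share of probes well above background in Cy5 ranged from 9.62% (13 °C and 400 µatm, replicate 3) to 25.4% (18 °C and 400 µatm, replicate 2), and in Cy3 from 20.2% to 37.8%. The number of arrays limits the precision.

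A limma model of the 4 group means was fitted to all 12 arrays, with Benjamini-Hochberg adjustment over targets and a threshold of 0.05 in each of 8 comparisons. These were the temperature effect averaged over pCO2, the pCO2 effect averaged over temperature, their interaction, larvae under both stressors against larvae under neither, and the effect of each factor at each level of the other. The p-values rest on the spread between the replicate arrays of a group, from cultures that the labels describe as separate. Most arrays of a group shared a slide and a scan day, so this spread holds only part of any slide or day variation. Differences between groups can hold more of it. Without a term for replicate number, the spread includes the differences between replicate numbers. With such a term these are taken out. The comparisons, the main settings and the other settings of normalization, filtering and blocking were chosen before the data were examined, except where the closing section says otherwise. A further fit, also chosen then, treated the replicate number as a block. Whether replicate numbers pair the cultures was checked: the deviations from the group mean correlated across targets at r = 0.59 to 0.80 in all 18 pairs of arrays that share a replicate number and at -0.60 to -0.085 in the 36 pairs that do not. Counts with this block are therefore given beside those without it. Means of a family on the arrays were compared by 2-sided exact permutation of the group labels within replicate numbers. The 216 permutations can give no p below 0.00926. They do not keep the arrays of a slide together, so their p-values make no allowance for a slide effect.

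Slides and scan days were read as codes from the files. The replicate 1 arrays of all 4 groups were scanned on 1 day, on 2 slides. Each of the other 4 slides held replicates 2 and 3 of 1 group. Every slide held larvae of 1 temperature only. In replicates 2 and 3 each slide also held 1 pCO2 level and had a scan day of its own. On the replicate 1 slides, position coincided with pCO2: both 400 µatm arrays lay in position 2 and both 1100 µatm arrays in position 1. Replicate 2 lay in position 2 and replicate 3 in position 1 on the other slides.

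The gene lists and named genes fixed beforehand rested on gene names. The rule for named genes took, in each comparison, the targets with the largest changes past the threshold whose arrays did not overlap between the sides and which had an informative name, with up to 4 members of each list and the spicule matrix proteins SM30, SM37, SM50 and MSP130, the histones, HSP70 and HSP90. None of the 28819 SPU identifiers matched the reference table of 33503 genes (0 matches), so neither the 24 lists nor this rule could be applied by name, and no value is given for the spicule matrix proteins. Instead, 64 protein families were read from the translated probe sequences. A probe was assigned to a family if at least 12 of 19 residues in 1 reading frame were identical, without gaps, to 1 of 71 conserved reference proteins, or if it held a motif of the family. The reference proteins were written from general knowledge and not from a database. The families were fixed after the files were at hand but before any signal was compared between groups. With the union of the 4 core histone classes added as a family, 16 had at least 5 tested targets: core histones together, histones H2A, H2B, H3 and H4, tubulin, EGF-like repeats, ribosomal proteins, the calmodulin family, the HSP70 family, actin, C2H2 zinc fingers, scavenger receptor cysteine-rich domains, cytochrome P450s, Arf GTPases and protein kinases. The histone targets therefore enter the tests both in their class and in the union. A family contains targets whose probes encode such a protein, not genes named as such by the array.

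Shifts of families were tested with camera of limma at a preset correlation of 0.01 between members, adjusted over the 16 families in each comparison. Camera with an estimated correlation and fry, which tests whether the members of a family move on balance in 1 direction, were run beside it. Other alternatives were the processed intensities of Feature Extraction, the authors' series table, median centring, array weights, no filter and a stricter filter on signal, the brightest probe of each target, slide or scan day as a block, targets sharing a probe sequence merged, and each array left out in turn. In simulated changes of 200 of 10426 targets in the temperature comparison, 16% of 1.5-fold changes and 79.5% of 2-fold changes were called without the replicate block, and 78% and 97.5% with it. Of the unchanged targets, 0 and 1 were called without the block and 6 and 8 with it. The simulated data held replicate effects and independent noise but no slide effect, so they favour the fit with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.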

Results

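The data are log2 ratios of the RNA of each larval culture (Cy5) over a common pool of all samples (Cy3) on 12 arrays, 3 replicate cultures in each of 4 groups: 13 °C and 400 µatm, 13 °C and 1100 µatm, 18 °C and 400 µatm, and 18 °C and 1100 µatm. Single arrays are named by temperature, pCO2 and replicate number, as in 13/400 replicate 1. The question stated by the series is how warming and raised pCO2 act together on gene expression in larvae. Of the 10430 targets tested, the Cy5 signal was well above background on no array of a group for 922 targets at 13 °C and 400 µatm, 543 at 13 °C and 1100 µatm, 120 at 18 °C and 400 µatm and 273 at 18 °C and 1100 µatm. Signals were saturated on every array of a group for 3, 10, 20 and 10 targets in the same order. Families of targets are named by the protein that their probes encode. Near-identical gene copies, as among histones, share probes, so a target of these families does not stand for 1 gene.

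Larvae of 1 replicate number resembled each other more than larvae of 1 treatment. Replicate number accounted for 66.0% of the sum of squares over all targets, temperature for 7.27%, pCO2 for 6.58% and their interaction for 3.01%. The first component held 46.6% of the variance and the second 24.0%, and replicate number explained 89.2% and 98.0% of them. The third component held 9.25%, of which the 4 groups explained 75.2% (temperature 45.9%, pCO2 26.7%). Correlations between arrays across targets ranged from -0.54 to 0.77, and 11 pairs of arrays lay below -0.3. Genes are not independent replicates in these correlations. The labels give the same dye to the culture on every array, so all ratios were kept in that direction.

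**Figure D1:**
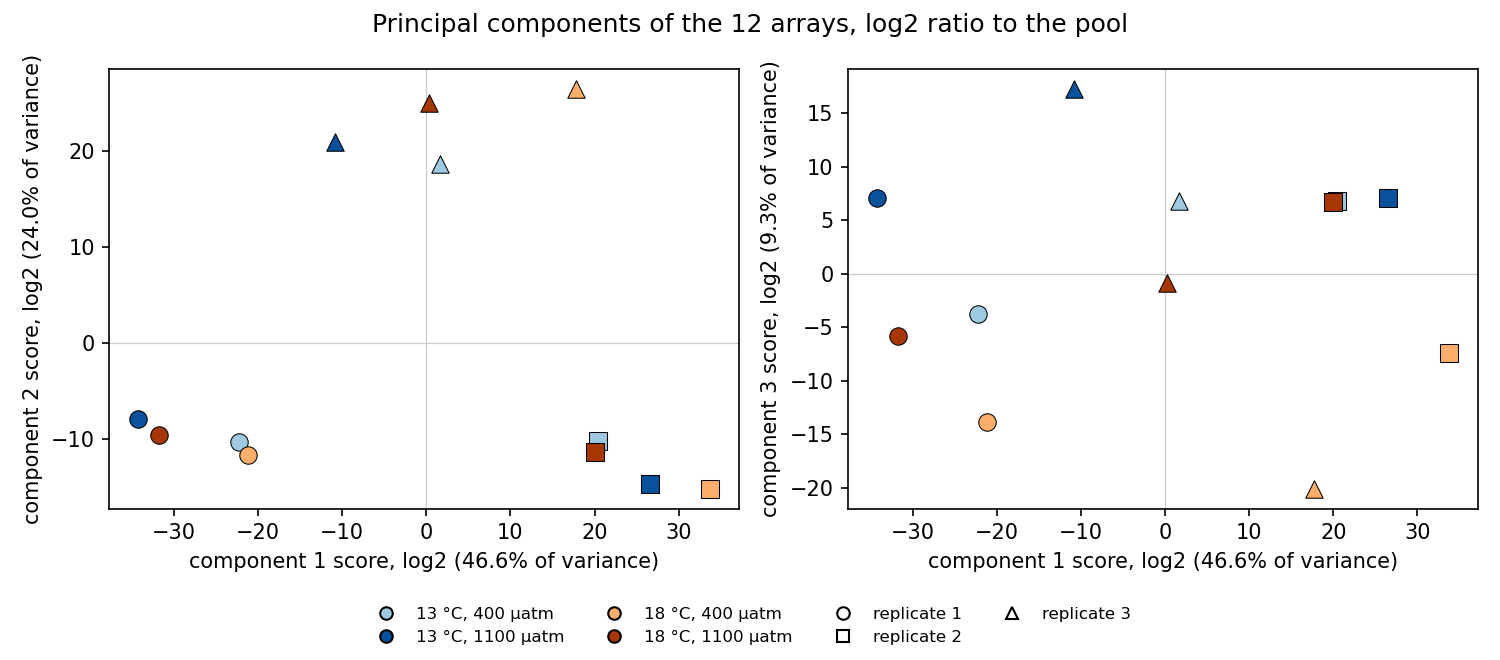
Positions of the 12 arrays on principal components 1 and 2 (left) and 1 and 3 (right) of the log2 ratios, with each axis giving the component's share of the variance. Colours are the 4 groups and markers the replicate numbers; the arrays cluster by replicate number on components 1 and 2 (46.6% and 24.0%), and component 3 (9.25%) follows the groups.

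The first comparison asks what warming from 13 to 18 °C changed, averaged over both pCO2 levels. Targets encoding core histones, the proteins around which DNA is wound in chromatin, were lower at 18 °C: the median log2 difference over 139 targets was -0.24, with 132 below 0 and 7 above. All 4 classes shared this direction, with medians of -0.21 for H2A (24 of 30 targets below 0), -0.11 for H2B (38 of 38), -0.29 for H3 (33 of 34) and -0.25 for H4 (37 of 37). At 400 µatm alone H3 did not: its mean log2 ratio was -0.19 at 13 °C and -0.13 at 18 °C. Targets encoding tubulin, the subunit of microtubules and of the axonemes of cilia, were higher at 18 °C, with a median of 0.18 and 35 of 41 targets above 0. Targets with EGF-like repeats, a module of many extracellular and membrane proteins, were lower (median -0.17, 27 of 31 below 0). Ribosomal protein targets were slightly higher (median 0.06, 31 of 37 above 0), and targets of the calmodulin family, calcium-binding proteins, were lower (median -0.13, 9 of 10 below 0).

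Camera called 9 of the 16 families for temperature, 7 lower and 2 higher. The adjusted p was 3.02e-20 for the core histones (adjusted p = 0.273 with an estimated correlation), 3.06e-05 for H2A, 6.67e-11 for H2B, 1.74e-11 for H3, 1.32e-10 for H4, 1.24e-08 for tubulin, 0.000129 for EGF-like repeats, 0.0203 for ribosomal proteins and 0.0233 for the calmodulin family. The smallest adjusted p of any family was 0.273 with an estimated correlation, so no call held under it. The calls of the histones, tubulin and EGF-like repeats were kept when any single array was left out, but their medians moved. They ranged from -0.35 to -0.134 for the core histones, -0.25 to -0.0997 for H2A, -0.198 to -0.047 for H2B, -0.383 to -0.209 for H3, -0.433 to -0.126 for H4, 0.109 to 0.345 for tubulin and -0.208 to -0.102 for EGF-like repeats. The call of EGF-like repeats was lost with scan day as a block (adjusted p = 0.0659), where tubulin turned to -0.19. That of ribosomal proteins (median 0.0225 to 0.083 with 1 array left out) was lost with Feature Extraction intensities (adjusted p = 0.116) and without 13/400 replicate 1 (0.296), 13/1100 replicate 1 (0.124), 13/1100 replicate 3 (0.0687) or 18/1100 replicate 3 (0.0804). That of the calmodulin family (median -0.251 to -0.0171 with 1 array left out) was lost with median centring (0.317) and without 13/400 replicate 2 (0.223), 13/1100 replicate 2 (0.372), 18/400 replicate 1 (0.308), 18/1100 replicate 1 (0.373) or 18/1100 replicate 3 (0.0804).

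The mean log2 ratio of the core histones was -0.05 ± 0.02 at 13 °C and 400 µatm, 0.13 ± 0.32 at 13 °C and 1100 µatm, -0.15 ± 0.04 at 18 °C and 400 µatm and -0.22 ± 0.17 at 18 °C and 1100 µatm (SD, n = 3). Their mean difference between temperatures was -0.26 on the replicate 1 arrays, which shared a scan day, -0.07 for replicate 2 and -0.34 for replicate 3, and it was below 0 in 6 of 6 pairs of arrays of 1 replicate number and pCO2 level. A 2-sided exact permutation test within replicate numbers gave p = 0.0648 (0.207 adjusted over 16 families). For H2A alone, also lower in 6 of 6 pairs, the exact permutation p was 0.00926, the smallest possible, and 0.148 adjusted. The same test gave 0.0278 for H2B (6 of 6 pairs lower), 0.111 for H4 (5 of 6) and 0.194 for H3 (4 of 6). Adjusted, these were 0.207, 0.207 and 0.259. The pairs are not independent, since replicates 2 and 3 of a group shared a slide. Each slide held 1 temperature, and the permutations move arrays between slides. These exact p-values therefore make no allowance for a slide effect. The tubulin difference was -0.18 on the replicate 1 arrays against 0.39 and 0.57 for replicates 2 and 3, so it did not hold on the shared scan day; its exact permutation p was 0.111.

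The H2B target with the smallest p had a log2 difference of -0.49 ± 0.11 (SE without the block; adjusted p = 0.749, or 0.0307 with the replicate block), the H2A target -0.38 ± 0.13 (1, or 0.0499), the H3 target -0.35 ± 0.15 (1, or 0.199) and the H4 target -0.37 ± 0.13 (1, or 0.133). The 2 tubulin targets with the smallest p had 0.57 ± 0.17 and 0.74 ± 0.27. Heat shock proteins, chaperones that help other proteins fold, showed no call: the 7 targets of the HSP70 family all lay below 0 with a median of -0.36 and an adjusted p of 0.0695. With the replicate block this became 0.0169 (adjusted p = 0.466 with an estimated correlation), and the differences were -0.79, -0.06 and -0.04 for replicates 1, 2 and 3. The HSP90 targets had -0.24 ± 0.27 and 0.09 ± 0.20.

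**Figure D2:**
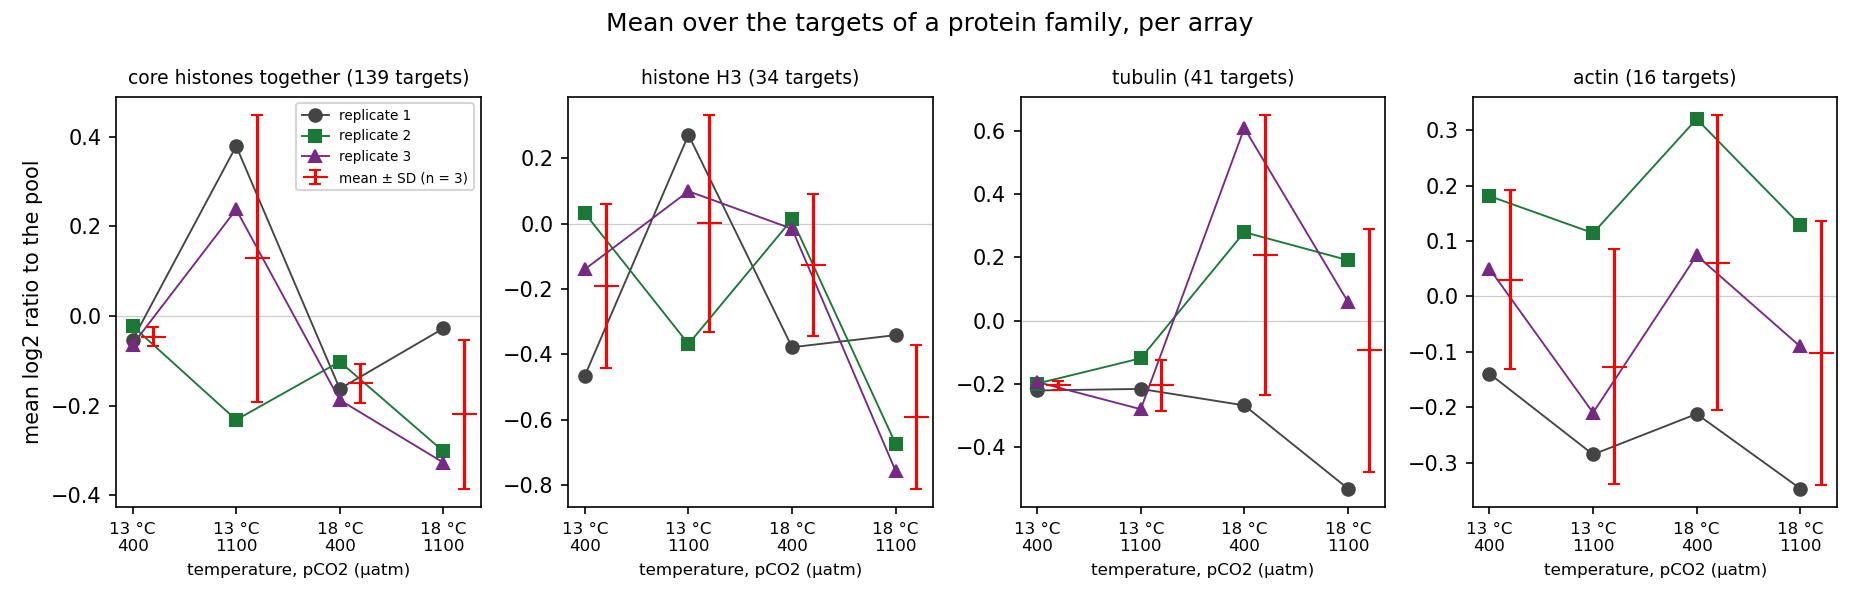
Mean log2 ratio (Cy5 over Cy3) on each array of the targets encoding core histones (139), histone H3 (34), tubulin (41) and actin (16), by group; lines join arrays of 1 replicate number, and red marks give the group mean and SD (n = 3). The core histones are lowest at 18 °C and 1100 µatm (-0.22 ± 0.17), H3 lies lowest there too (-0.59 ± 0.22), and vertical scales differ between panels.

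For single targets, limma without a block called 0 of 10430 for temperature, with 445 at an unadjusted p under 0.05. Adjusted over the list alone, 8 of the 38 H2B targets passed as lower. With replicate number as a block, 164 targets passed, 91 higher and 73 lower at 18 °C, with 2002 at an unadjusted p under 0.05. Among these 164 the median size of the change was 0.47 (log2), and 154 had the same sign in 6 of 6 pairs. The 73 lower targets included 9 encoding H2B and 4 encoding H2A, and none was an H3 or H4 target: 13 of the 73 were core histones, against 139 of all 10430 tested, with copies that share probes counted separately. Adjusted over the list alone, 27 core histone targets passed as lower with the block and 12 tubulin targets as higher. None of the 91 higher targets belonged to any of the families. Left out 1 at a time, 13/400 replicates 1, 2 and 3 gave 80, 68 and 32 targets with the block, and 13/1100 replicates 1, 2 and 3 gave 68, 646 and 55. Without 18/400 replicates 2 and 3 there were 33 and 56, and without 18/1100 replicates 1, 2 and 3 there were 104, 46 and 50. With median centring the count was 18, with Feature Extraction intensities 37 and without a filter 376. With slide as a random block it was 429, but the estimated correlation within slides was negative (-0.145). Each slide held 1 temperature, so a negative value narrows the error of the temperature difference and does not allow for a slide effect. The count was 63, 1 and 4 without the arrays of replicates 1, 2 and 3.

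Of the 164 targets, 20 had no overlap between the 6 arrays of each temperature. The first 3 targets described here were picked from these 20 by no rule fixed beforehand. The largest rise among the 164 was 0.99, in another target. Among the 20, SPU_027673 had a log2 difference of 0.91 ± 0.13 (SE with the block), with an adjusted p of 0.0104 (0.518 without the block). Its mean log2 ratios were -0.75 ± 0.14 and -0.88 ± 0.07 at 13 °C and -0.0061 ± 0.07 and 0.20 ± 0.49 at 18 °C, at 400 and 1100 µatm (SD, n = 3). Its brightest probe was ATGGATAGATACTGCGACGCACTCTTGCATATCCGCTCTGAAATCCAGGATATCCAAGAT, with 0.92. SPU_027336 had 0.81 ± 0.10 (adjusted p = 0.00619 with the block, 0.518 without), from -0.33 ± 0.31 and -0.51 ± 0.22 at 13 °C to 0.42 ± 0.21 and 0.36 ± 0.21 at 18 °C, and its Cy5 signal was well above background on 1 and 2 of the 3 arrays at 13 °C and on all at 18 °C, so the means at 13 °C lie partly at background and the difference has no exact size. SPU_002075 had -0.52 ± 0.11 (adjusted p = 0.042 with the block, 0.814 without), from 0.02 ± 0.09 and 0.25 ± 0.23 at 13 °C to -0.55 ± 0.37 and -0.23 ± 0.10 at 18 °C. At 13 °C and 400 µatm its Cy5 signal was well above background on 1 of 3 arrays. On the replicate 1 arrays, which shared a scan day, its values at 13 and 18 °C were -0.08 and -0.11 at 400 µatm, and 0.27 and -0.12 at 1100 µatm. Over all other settings its difference ranged from -0.81 to -0.21. SPU_007484 was also chosen after its values were seen, as the largest fall: -0.92 ± 0.09 with the block (adjusted p = 0.00285, or 1 without it). It was assigned to the cyclophilins, prolyl isomerases that help proteins fold, by 1 probe only (15 of 19 residues). That probe was its dimmest (mean log2 Cy5 of 8.02), with a difference of -0.60. The brighter probes, without a match to the family, had -0.99 to -1.08. Its means were 0.05 ± 0.64 and 0.26 ± 0.83 at 13 °C and -0.65 ± 0.66 and -0.88 ± 0.97 at 18 °C, and it was lower at 18 °C in 6 of 6 pairs. None of the first 3 has a gene name in the files.

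**Figure D3:**
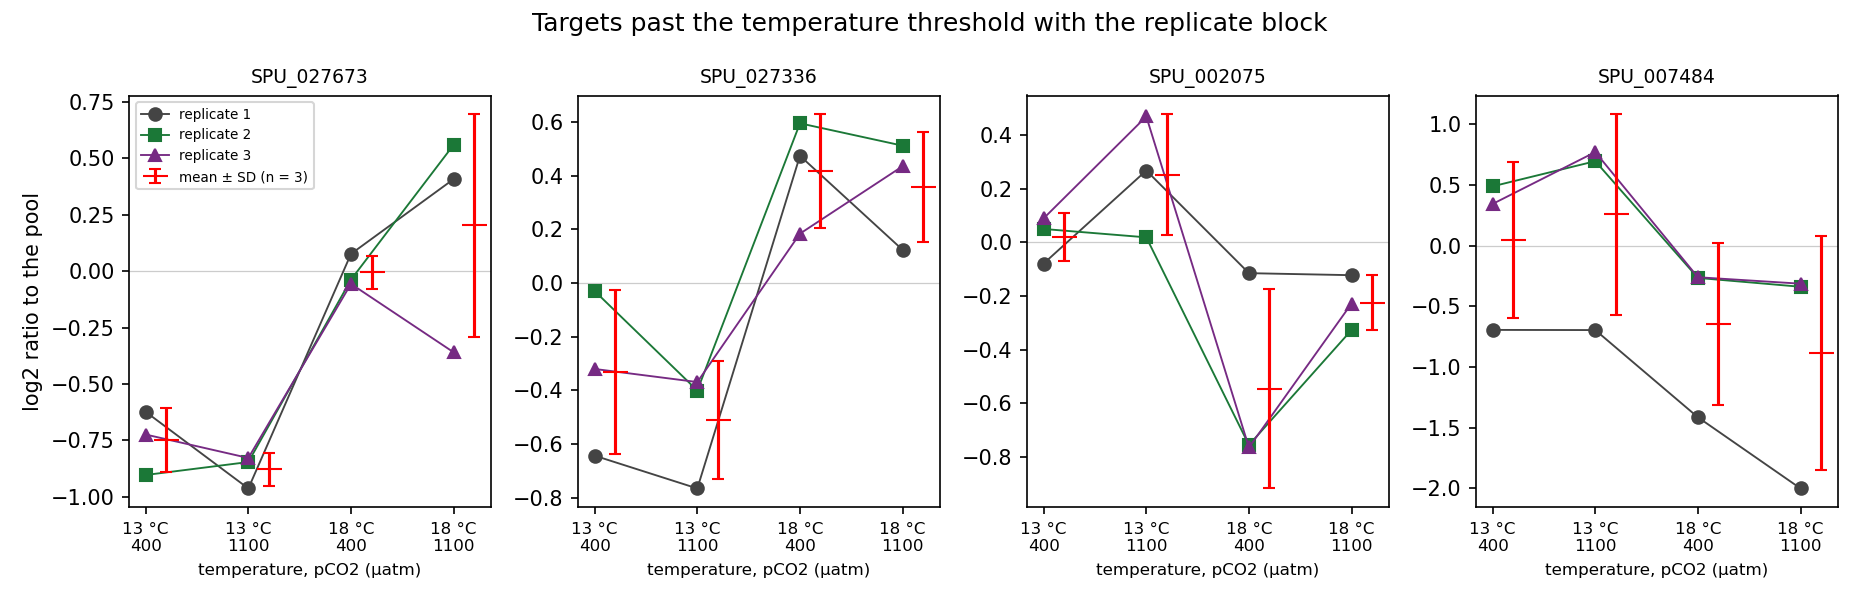
Log2 ratio (Cy5 over Cy3) on each array of SPU_027673, SPU_027336, SPU_002075 and SPU_007484, by group; lines join arrays of 1 replicate number and red marks give the group mean and SD (n = 3). SPU_007484 differs more between replicate numbers (SD of 0.64 to 0.97 within groups) than the other targets do, and falls with temperature in each of them.

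The second comparison asks what raising pCO2 from 400 to 1100 µatm changed, averaged over both temperatures. Targets encoding actin, the protein of thin filaments, were lower at 1100 µatm, with a median log2 difference of -0.09 and 14 of 16 targets below 0. Tubulin targets were lower (median -0.15, 31 of 41 below 0), and all 10 targets of the calmodulin family lay below 0 (median -0.20). The medians of the histone classes differed in sign: H3 targets were lower (median -0.19, 26 of 34 below 0), while H4 (median 0.22, 29 of 37 above 0), H2B (0.10, 25 of 38) and H2A (0.09, 21 of 30) were higher. Differences between classes were not tested. The mean differences of H3 and H4 had the same sign in replicate 1 (0.39 and 0.43) and replicate 2 (-0.54 and -0.17), and opposite signs in replicate 3 (-0.25 and 0.28). Some families had too few tested targets for a test of the family. The 2 targets encoding the mitochondrial ATP synthase had -0.48 ± 0.21 and -0.21 ± 0.21, the target encoding the ADP/ATP translocase had -0.29 ± 0.26, and 4 targets encoding glycolytic enzymes lay between -0.24 and -0.04. None of these passed (for the first 3, SE without the block, adjusted p = 1 each, or 0.141, 0.377 and 0.153 with the replicate block).

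Camera called 7 families for pCO2. The adjusted p was 0.00789 for actin and for the calmodulin family, 0.000163 for tubulin, 2.25e-07 for H3, 0.00166 for H4, 0.0403 for H2B and 0.0459 for H2A, and for each of them the adjusted p was 0.69 with an estimated correlation. With the replicate block, H2B (0.114) and H2A (0.0576) no longer passed, and ribosomal proteins passed as lower (median -0.04, adjusted p = 0.0369, against 0.0586 without it; adjusted p = 0.596 with the block and an estimated correlation). Actin targets were lower in each replicate number, with mean differences of -0.14, -0.13 and -0.21, and in 6 of 6 pairs of arrays. The exact permutation p for actin was 0.00926, the smallest possible, and 0.148 adjusted over 16 families. The pairs are not independent, since replicates 2 and 3 of a group shared a slide. In these replicates pCO2 cannot be told apart from slide and scan day, and in replicate 1 not from position on the slide. The H3 difference was 0.39 on the replicate 1 arrays, which shared a scan day, against -0.54 and -0.25 for replicates 2 and 3. The H4 difference was 0.43, -0.17 and 0.28, that of tubulin -0.13, -0.0043 and -0.32, and that of the calmodulin family -0.26, 0.02 and -0.24.

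Each of these calls was lost when some single array was left out. Without 18/1100 replicate 1 the adjusted p was 0.24 for actin, 0.262 for tubulin, 0.578 for H4 and 0.27 for the calmodulin family, and without 13/1100 replicate 2 it was 0.117 for H3. Actin was also lost without 13/1100 replicate 1 (0.077) or 18/400 replicate 2 (0.124), with Feature Extraction intensities (0.143) and with scan day as a block (0.15). Tubulin was also lost without 18/400 replicate 3 (0.107), H4 without 13/1100 replicates 1 or 3 (0.483 and 0.111), and the calmodulin family with median centring (0.0683) and without 13/400 replicate 2 (0.085), 13/1100 replicate 1 (0.077) or 18/400 replicate 2 (0.0546). H2A was lost without any of 6 arrays (18/400 replicates 2 and 3, 13/400 replicate 3, 13/1100 replicate 1, 18/1100 replicates 1 and 2; 0.0785 to 0.49) and H2B without any of 7 (13/400 replicate 1, 13/1100 replicates 1 and 3, 18/400 replicates 1 and 3, 18/1100 replicates 1 and 2; 0.0568 to 0.572). With targets that share a probe sequence merged, H2A was lost (0.324), and so was H2B (0.824), whose direction in the test turned to lower. H2B was also lost with median centring (0.0917), H2A with scan day as a block (0.39), and both with the authors' values (0.245 for H2A and 0.062 for H2B). Over the single arrays left out, the medians ranged from -0.302 to -0.1 for H3, 0.0984 to 0.437 for H4, 0.0518 to 0.173 for H2B, 0.0416 to 0.136 for H2A, -0.258 to -0.0424 for tubulin, -0.311 to -0.0552 for the calmodulin family and -0.136 to -0.0614 for actin.

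For single targets, limma called 0 of 10430 for pCO2, with 213 at an unadjusted p under 0.05. With the replicate block it again called 0, with 1674 at an unadjusted p under 0.05. Adjusted over the list alone, 4 of 16 actin targets passed as lower with the block. One of these 4, SPU_004196, had -0.49 ± 0.09 (SE with the block; 0.25 without it), and the highest value of the family, in a target that was not among them, was 0.26 ± 0.10 (0.12 without it). The count with the block was 777 (711 higher, 66 lower) without 13/1100 replicate 2, 5 without 18/1100 replicate 1, and 1 without 13/400 replicate 1. HSP70 and HSP90 targets with the smallest p had 0.34 ± 0.30 and 0.41 ± 0.27. A target with repeats of the residues QPG, a pattern also found in spicule matrix proteins, had -0.32 ± 0.36; it is not identified further.

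The third comparison asks whether the pCO2 effect differed between temperatures. For targets encoding H3, the pCO2 effect at 18 °C minus that at 13 °C had a median of -0.72 (log2), below 0 for 34 of 34 targets. The call by camera (adjusted p = 7.53e-36) was lost with an estimated correlation (adjusted p = 0.209 with an estimated correlation), and the 2-sided exact permutation p was 0.12 (0.79 adjusted over 16 families). The mean log2 ratio of H3 was -0.19 ± 0.25 at 13 °C and 400 µatm, 0.00056 ± 0.33 at 13 °C and 1100 µatm, -0.13 ± 0.22 at 18 °C and 400 µatm and -0.59 ± 0.22 at 18 °C and 1100 µatm (SD, n = 3). The interaction was also below 0 for tubulin (median -0.30, 37 of 41 targets), H2B (-0.19, 36 of 38) and the core histones together (-0.19, 108 of 139). The H3 target with the smallest p had an interaction of -1.07 ± 0.36 (SE, adjusted p = 1).

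The other 3 families called by camera were the core histones (adjusted p = 2.64e-15), H2B (1.38e-07) and tubulin (2.24e-07). With an estimated correlation the adjusted p was 0.454 for the core histones, 0.454 for H2B and 0.641 for tubulin. The H3 interaction was -0.70, -0.29 and -0.98 for replicates 1, 2 and 3, the first on the shared scan day, and that of the core histones -0.30, 0.0093 and -0.44. The tubulin interaction was -0.27, -0.17 and -0.46, and its call was lost without 18/400 replicate 3 (adjusted p = 0.103) or 18/1100 replicate 1 (0.176). The calls of H3, H2B and the core histones were kept when any single array was left out, while the medians ranged from -0.904 to -0.532 for H3, -0.275 to -0.0868 for H2B and -0.344 to -0.0757 for the core histones (tubulin: -0.541 to -0.105). For single targets, limma called 0 of 10430 without the block (80 at an unadjusted p under 0.05) and 0 with it (596).

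The fourth comparison sets larvae under both stressors against larvae at 13 °C and 400 µatm. H3 targets were lower by a median of -0.51 (30 of 34 below 0), and calmodulin family targets by -0.33 (9 of 10 below 0). The core histones together, H2B and H4 were also called lower, although their medians were -0.06, -0.0017 and -0.02, and with an estimated correlation none of the 3 passed (adjusted p = 0.534, 0.631 and 0.708). Camera gave an adjusted p of 3.43e-25 for H3 (adjusted p = 0.466 with an estimated correlation) and 1.52e-05 for the calmodulin family (0.534), and with the replicate block H4 no longer passed (0.053) while actin (median -0.12) and H2A (median 0.0062) passed as lower (0.0115 each; adjusted p = 0.456 and 0.571 with an estimated correlation). The H3 difference was 0.12 on the replicate 1 arrays and -0.70 and -0.62 for replicates 2 and 3, so it did not hold on the shared scan day. The calmodulin family difference was -0.61, -0.08 and -0.30 and its call was lost without 18/1100 replicate 1 (0.112). With 1 array left out, the medians ranged from -0.683 to -0.325 for H3 and from -0.651 to -0.0911 for the calmodulin family. The core histones and H2B were lost with scan day as a block (0.362 and 0.758), and the direction of the core histones in the test turned to higher. H4 was lost without 13/400 replicate 1 (0.276), 18/1100 replicate 2 (0.899) or 18/1100 replicate 3 (0.354), with Feature Extraction intensities (0.467), without a filter (0.0503) and with the authors' values (0.0522), and it turned to higher with scan day as a block (0.057). For single targets, limma called 0 of 10430 (165 at an unadjusted p under 0.05), and 0 with the block (1018).

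At 13 °C, 138 of 139 core histone targets had a higher level at 1100 than at 400 µatm, with a median of 0.17. H2B (0.15), H4 (0.20), H3 (0.18) and H2A (0.11) shared the direction, and actin targets were lower (-0.11, 11 of 16 below 0). Camera gave an adjusted p of 3.24e-13 for the core histones (adjusted p = 0.505 with an estimated correlation, the lowest of any family), 1.89e-10 for H2B, 4.57e-06 for H4, 6.34e-06 for H3, 0.00108 for H2A and 0.00444 for actin. Ribosomal proteins were also called lower (0.000725), with a median of -0.07. The core histone difference was 0.43 for replicate 1, -0.21 for replicate 2 and 0.30 for replicate 3, and its call was lost without 13/1100 replicate 1 (0.333), as were those of H2A (0.907), H3 (0.625), H4 (0.829), actin (0.559) and ribosomal proteins (0.417). H2A was also lost without 13/400 replicate 3 (0.15), H3 without 13/400 replicate 1 (0.86) and H4 without 13/1100 replicate 3 (0.312). Actin and ribosomal proteins were also lost without 13/400 replicates 2 and 3 or 13/1100 replicate 3 (0.0547 to 0.258), and both with median centring (0.0858 and 0.527), with Feature Extraction intensities (0.309 and 0.54) and with scan day as a block (0.291 and 0.496), and actin without a filter (0.119). The median of the core histones ranged from 0.0504 to 0.32 over the single arrays left out, that of H2B from 0.106 to 0.303, H4 from -0.029 to 0.613, H3 from -0.0042 to 0.315, H2A from 0.0258 to 0.189 and actin from -0.229 to -0.0788. With the replicate block the HSP70 family passed as higher (median 0.29, 0.0121 against 0.109 without it) and the calmodulin family as lower (median -0.15, 0.0385 against 0.109); for both the adjusted p was 0.602 with an estimated correlation. The limma count of single targets was 0 of 10430 (33 at an unadjusted p under 0.05), and 0 with the block (453).

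At 18 °C, H3 targets were lower at 1100 than at 400 µatm by a median of -0.58 (30 of 34 below 0), tubulin targets by -0.32 (34 of 41) and calmodulin family targets by -0.23 (10 of 10). The adjusted p from camera was 6.83e-23 for H3 (adjusted p = 0.567 with an estimated correlation, the lowest of any family), 1.44e-07 for tubulin and 0.0191 for the calmodulin family. The core histones together were called lower (0.0039, or 0.0565 with the replicate block), while their median was 0.01. The H3 difference was 0.04 for replicate 1 and -0.69 and -0.74 for replicates 2 and 3, and that of tubulin was -0.26, -0.09 and -0.55. The medians ranged from -0.759 to -0.446 for H3, -0.558 to -0.0781 for tubulin and -0.456 to 0.0222 for the calmodulin family when 1 array was left out. With scan day as a block the H3 call was lost and turned to higher (0.457). The tubulin call was lost without 18/400 replicate 3 (0.0739) or 18/1100 replicate 1 (0.239), that of the calmodulin family with median centring (0.107), with the authors' values (0.087) and without 18/400 replicates 2 or 3 or 18/1100 replicates 1 or 3 (0.0978 to 0.873), and that of the core histones without 18/1100 replicates 2 or 3 (0.204 and 0.164). Actin passed as lower with the replicate block (median -0.09, 0.0271 against 0.149; adjusted p = 0.649 with an estimated correlation). The limma count of single targets was 0 of 10430 (316 at an unadjusted p under 0.05), and 0 with the block (1774); adjusted over the list alone, 22 of 34 H3 targets passed as lower with the block and 0 without it.

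At 400 µatm, tubulin targets were higher at 18 than at 13 °C by a median of 0.39 (36 of 41 above 0), and the 2 with the smallest p had 0.81 ± 0.24 and 1.02 ± 0.39 (SE). H4 targets were lower (-0.25, 37 of 37 below 0), as were H2A (-0.17, 24 of 30), the core histones together (-0.11, 95 of 139) and targets with EGF-like repeats (-0.15, 25 of 31). H3 was not called, with mean differences of 0.09, -0.02 and 0.12 for replicates 1, 2 and 3. The adjusted p from camera was 1.78e-12 for tubulin (adjusted p = 0.537 with an estimated correlation, the lowest of any family), 4.64e-05 for H4, 0.00546 for the core histones, 0.00118 for EGF-like repeats and 0.0168 for H2A and for H2B (median -0.08). The core histones and H2B were lost without 13/400 replicate 2 (0.131 each) or 18/400 replicate 1 (0.274 and 0.804), and H2A without 13/400 replicates 1 or 2 or 18/400 replicates 2 or 3 (0.0621 to 0.459). All 3 were lost with Feature Extraction intensities (0.306), with median centring (0.167 to 0.749) and with the authors' values (0.124 to 0.4). EGF-like repeats were lost with the authors' values (0.192) and with scan day as a block (0.0786), as were the core histones (0.125) and H2A (0.831) with that block. Leaving out 1 array gave medians of 0.215 to 0.657 for tubulin, -0.353 to -0.139 for H4, -0.187 to -0.0751 for H2A, -0.137 to -0.0797 for the core histones and -0.275 to -0.143 for EGF-like repeats. With scan day as a block the tubulin call was lost and turned to lower (0.825). The tubulin difference was -0.05, 0.48 and 0.80 for replicates 1, 2 and 3, so it did not hold on the shared scan day. Adjusted over the list alone, 12 tubulin targets passed as higher with the replicate block. The limma count of single targets was 0 of 10430 (251 at an unadjusted p under 0.05), and 0 with the block (1656).

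At 1100 µatm, core histone targets were lower at 18 than at 13 °C, with a median of -0.26 and 6 of 139 above 0. H3 targets differed by a median of -0.66 (34 of 34 below 0), H4 by -0.24 (37 of 37), H2A by -0.19 (24 of 30) and H2B by -0.18 (38 of 38). Calmodulin family targets (-0.20, 9 of 10 below 0) and targets with EGF-like repeats (-0.11, 23 of 31) were lower too, and ribosomal proteins were higher by 0.07. Camera gave an adjusted p of 7.79e-37 for H3 and 7.12e-36 for the core histones, and for both the adjusted p was 0.0837 with an estimated correlation. It gave 2.55e-18 for H2B, 2.66e-10 for H4, 1.18e-05 for H2A, 0.00598 for the calmodulin family, 0.00312 for ribosomal proteins and 0.00918 for EGF-like repeats. With an estimated correlation no family passed, and 0.0837 was the smallest adjusted p of any family. Without 13/1100 replicate 1, H4 (0.128), H2A (0.138), ribosomal proteins (0.198) and EGF-like repeats (0.449) were lost. The calmodulin family was lost without 13/1100 replicate 2, 18/1100 replicate 1 or 18/1100 replicate 3 (0.0657 to 0.835), ribosomal proteins also without 13/1100 replicate 3 or 18/1100 replicate 3 (0.071 and 0.0657), and EGF-like repeats also without 13/1100 replicate 3 or 18/1100 replicates 2 or 3 (0.071 to 0.235), without a filter (0.329) and with scan day as a block (0.401). The authors' values also ended the call of ribosomal proteins (0.0821), and median centring that of the calmodulin family (0.0784). Medians with 1 array left out ranged from -0.563 to -0.137 for the core histones, -0.799 to -0.546 for H3, -0.342 to -0.0824 for H2B, -0.626 to 0.0227 for H4, -0.372 to 0.0091 for H2A, -0.486 to 0.0241 for the calmodulin family and -0.286 to 0.0013 for EGF-like repeats. The HSP70 family passed as lower with the replicate block (median -0.35, 0.0121 against 0.0714; adjusted p = 0.372 with an estimated correlation). The core histone difference was -0.41, -0.07 and -0.57 for replicates 1, 2 and 3, and that of H3 -0.61, -0.30 and -0.86, so both held on the shared scan day. The H3 target with the smallest p had -0.72 ± 0.21 (SE, adjusted p = 1). Adjusted over the list alone, 24 H3 targets passed as lower without the block and 26 with it, and 57 core histone targets passed with it.

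For single targets at 1100 µatm, limma called 0 of 10430 (236 at an unadjusted p under 0.05). With the block it called 1 (1074), SPU_007484, assigned to the cyclophilins by 1 probe, which was lower at 18 °C by -1.14 (log2, adjusted p = 0.0116). Without 18/1100 replicate 3 and without the block, 1 other target passed, as higher.

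The other 6 families were called in none of the 8 comparisons without the replicate block. Their smallest adjusted p was 0.0695 for the HSP70 family, 0.138 for C2H2 zinc fingers, 0.164 for cytochrome P450s, 0.458 for scavenger receptor cysteine-rich domains, 0.51 for protein kinases and 0.568 for Arf GTPases. With the block, the HSP70 family alone of these 6 passed in any comparison (smallest adjusted p = 0.0121). In all, camera called 50 of 128 combinations of family and comparison, and 0 with an estimated correlation or with fry. Of the 50 calls, 7 were of the core histones together. Another 5, 7, 7 and 6 were of H2A, H2B, H3 and H4, which hold the same targets.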

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

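The tests of the interaction in families were planned for lists by gene name and run on families read from probe sequences, a choice made after the identifiers were seen. Camera at its preset correlation called an interaction of temperature and pCO2 in 4 families, and none of the 4 calls held with an estimated correlation (adjusted p = 0.209 to 0.641 with an estimated correlation). The median pCO2 effect at 18 °C minus that at 13 °C was -0.72 (log2) for histone H3, with 34 of 34 targets below 0. It was -0.30 for tubulin, with 37 of 41 below 0, and -0.19 each for histone H2B and for the core histones together (-0.188 and -0.187), with 36 of 38 and 108 of 139 below 0. The 2-sided exact permutation p was 0.12 for H3, 0.38 for tubulin, 0.389 for H2B and 0.37 for the core histones (0.79 to 0.877 adjusted over 16 families). Leaving out 1 array gave medians from -0.904 to -0.532 for H3, -0.541 to -0.105 for tubulin, -0.275 to -0.0868 for H2B and -0.344 to -0.0757 for the core histones. The tubulin call was lost without 18/400 replicate 3 (adjusted p = 0.103) or 18/1100 replicate 1 (0.176). Groups of 3 arrays were not tested for outliers.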

How the results depend on the processing

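Slide and scan day as random blocks and scan day as a block for families were chosen after seeing the data. So were dropping the replicate 1 scan day, the targets of the series table alone and merged copies. The same holds for every setting that combines the replicate block with another choice. Fry was planned with a directional and a mixed p, of which only the directional p is used here. Limma called 0 targets under each scaling, filter, weighting, slide, scan day and series-table setting, in those of the 8 comparisons that the setting could estimate. Exceptions were the planned replicate block, which gave 164 for temperature and 1 for temperature at 1100 µatm, and leaving out 1 array, which gave 0 to 1 in both. With slide as a block only the interaction and the pCO2 comparisons could be estimated, so no temperature effect was tested there. With the replicate block, temperature had 164 targets, and 429 with slide as a random block. The correlation within slides was negative there (-0.145), so the 429 does not allow for a slide effect. The count was 37 with Feature Extraction intensities, 18 with median centring, 376 without a filter, and 63, 1 and 4 without the arrays of replicates 1, 2 and 3. Leaving out 1 array gave 32 to 646. It stayed within 1.5 times of 164 with the authors' values, the strict filter, the brightest probe, array weights and merged copies (134 to 188). The authors' values and the strict filter covered far fewer targets than the 10430 of the main fit, while the fit without a filter covered all 28819. A similar count there is a different share of the targets tested, with a different adjustment, so it does not show an unchanged result. With the block, pCO2 had 0, and 1 with median centring, 7 without a filter, 6 without the replicate 1 arrays and 0 to 777 without 1 array. The count of 50 calls among 128 combinations of family and comparison fell to 0 with an estimated correlation and with fry, without the block and with it, and to 0 with the block, merged copies and an estimated correlation. In the other settings it was 34 to 58. For each of the 50 calls the estimated correlation was above the preset 0.01 (0.0852 or more), which widens the test; for the other changes the cause was not tested. With scan day as a block, which leaves the replicate 1 arrays to estimate temperature and pCO2, tubulin reversed to -0.19 for temperature and -0.038 for temperature at 400 µatm. H3 reversed to 0.38 for pCO2, 0.14 for both stressors and 0.025 for pCO2 at 18 °C. For both stressors the test direction of the core histones (adjusted p = 0.362) and H4 (0.057) turned to higher. Leaving out 1 array was followed in 43 of the 50 medians: 38 changed over 1.5 times, and 7 of these lay on both sides of 0. For pCO2 at 13 °C, H3 ranged from -0.0042 (without 13/400 replicate 1) to 0.31 and H4 from -0.029 (without 13/1100 replicate 1) to 0.61. For temperature at 1100 µatm without 13/1100 replicate 1, H4 was 0.023 (range from -0.63), H2A 0.0091 (from -0.37) and EGF-like repeats 0.0013 (from -0.29). Without 18/1100 replicate 1 the calmodulin family was 0.022 for pCO2 at 18 °C (range from -0.46) and 0.024 for temperature at 1100 µatm (from -0.49). Signal over background limits all of these: 9.62% to 25.4% of probes were well above background in Cy5, and 10430 of 28819 targets could be tested.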

Other observations

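The tests of shared copies, of weak labelling, of scan day or slide and of position with a pCO2 effect taken off, and all comparisons between replicate numbers, were chosen after the results were seen. Averaged over the 4 groups, arrays of different replicate numbers differed in many targets. Whether these differences held within each group was not tested. All replicate 1 arrays had a scan day and slides of their own, so a difference from replicate 1 cannot be told apart from scan day and slide. Replicates 2 and 3 lay in different positions on the slides they shared, so their difference includes any position effect. With group as a term in limma, 5346 of 10430 targets differed between replicates 2 and 1 (2517 higher, 2829 lower in replicate 2), 3987 between 3 and 1 and 3507 between 3 and 2. HSP70 family targets, heat-inducible and constitutive chaperones, were lower in replicate 2 than in replicate 1 by a median of -1.19 (log2), with 6 of 7 passing as lower, and lower in replicate 3 by -0.96, also with 6 of 7. The size varied by group. The family's mean log2 ratio was 1.29, -0.33 and -0.12 for replicates 1, 2 and 3 at 13 °C and 1100 µatm. At 18 °C and 1100 µatm it was 0.16, -0.32 and -0.0064. H4 targets were lower in replicate 2 than in replicate 1 by -0.75 (27 of 37 passing). Calmodulin family targets were higher by 0.63 (8 of 10 passing), tubulin targets by 0.38 (13 higher and 3 lower) and actin targets by 0.24 (8 of 16 passing). Camera gave an adjusted p of 0.00307 for the HSP70 and calmodulin families, 2.75e-06 for H4, 0.00971 for tubulin and 0.00934 for actin between replicates 2 and 1. With an estimated correlation these were 0.435 for actin and 0.851 for the other 4. Between replicates 3 and 2, which shared slides and days, camera did not call the HSP70 family (median 0.23, adjusted p = 0.423), tubulin (0.04, 0.869) or actin (-0.29, 0.101). It called H4 as higher in replicate 3 (0.32, 0.00325) and the calmodulin family as lower (-0.33, 0.0456), with 0.965 and 0.824 with an estimated correlation. The labels do not say what the replicate numbers have in common, such as parents or a spawning day.

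Core histones were lower at 18 °C, by a mean of -0.226 (log2) over 139 targets (exact permutation p = 0.0648, or 0.207 adjusted over 16 families). With targets that share a probe sequence merged into 78, the mean was -0.261 (exact permutation p = 0.0278, or 0.148 adjusted). Repeated counting of such copies therefore did not produce the mean. The merging joined identical sequences only, so it does not decide about copies with nearly identical probes. Of 10000 random sets matched on signal, 0% had a mean as low (lowest -0.11), which argues against a dye bias shared by other targets of that signal. The 0% is not a p-value. Loess had already fitted the intensity trend, and the sets took single targets, while histone copies share probes and move together. On the shared scan day the difference was -0.258 against an SD of 0.138 over replicate numbers, which argues against scan day. Slide and temperature cannot be told apart, since 0 slides held larvae of both temperatures, and the design names temperature, under which 6 of 6 pairs were lower. Neither these pairs nor the exact permutations allow for a slide effect. Warming may lower core histone transcripts, as a hypothesis found on these data, and a slide effect stays open beside it.

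The pCO2 count with the replicate block was 0 with all arrays and 777 without 13/1100 replicate 2. Weak labelling of that array is argued against by its share of probes well above background in Cy5, 21.6%, which lies inside the range of the others. Exchanging its label with that of 13/400 replicate 2 lowered the residual sum of squares to 0.923 of its value, the lowest of 18 exchanges within replicate numbers; 1 other exchange also fell below 1 (0.98). A label exchange could account for this and stays open, as does a difference in that culture itself, which was not tested. The labels were kept as given.

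Arrays of 1 replicate number deviated together in all 4 groups. Position on the slide is argued against, since the position difference in replicate 1 followed the difference between replicates 3 and 2 with a slope of only 0.167 across targets, where position as the whole source needs a slope near 1. Position coincided with pCO2 in replicate 1, so this difference includes a pCO2 effect; with the pCO2 effect of replicates 2 and 3 taken off, the slope was 0.067. Scan day or slide is argued against as the whole source, since 3507 targets differed between replicates 2 and 3, which share slides and days. The temperature effect correlated across targets with the difference between replicates 1 and 2 at r = -0.248, and 61 of 100 random relabelings gave an r as large, so whether warming moves larvae along the same axis stays open. The pCO2 effect correlated with that difference at r = 0.484, and with the difference of replicates 2 and 3 at r = -0.309; neither was tested by relabeling. A biological difference between the cultures of each number, such as parents, is a candidate explanation that was not tested.

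Other splits of the arrays give the counts a scale. For temperature without a block the count was 0, so 100 of 100 splits gave as many, and the highest other was 2061. For pCO2 (0; 100 of 100) the highest other was 2321 and for the interaction (0; 100 of 100) 2715. A count of 0 is reached by every split whatever the data, so these splits say nothing about chance. Over 100 targets were called by 2, 3 and 2 of these splits, which points to a structure of the samples, as the share of replicate number in the sum of squares (66.0%) shows. For larvae under both stressors and for each factor at 1 level of the other, the count was 0 and the highest other 0, and the 10 splits (10 of 10 with as many) are too few for a share under 0.05. With the replicate block, temperature gave 164 targets against 6 in the highest other split within replicate numbers, so 1 of 100 splits, the real one, gave as many. The real labels keep replicates 2 and 3 of a slide in 1 group, which the random splits need not do. The low counts of the other splits therefore cannot tell temperature from slide. With the block pCO2 gave 0 against a highest other of 100, and the interaction 0 against 311, and counts of 0 again say nothing about chance.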
